A study of Gallus gallus with 9 samples.

How the data were processed

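RNA was measured in 9 libraries of chicken primordial germ cells: 3 with a control vector, 3 labelled LIN28A knockout and 3 labelled LIN28B knockout. Per the labels' protocols, RNA was extracted with a Nucleospin RNA Plus kit, the molecule was poly(A) RNA, and libraries were made with a NEBNext Ultra Directional kit. The sample descriptions of the libraries labelled LIN28B knockout name the result table of LIN28A knockout and not that of LIN28B knockout, and the cause is not known. The labels do not say how the knockouts were made, nor whether libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

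The deposited counts are whole numbers per Ensembl gene, 1 table per library. Per the submitters' processing notes, HISAT2 2.1.0, featureCounts 2.0.3, DESeq2 1.36.0 and edgeR 3.38.4 were used with the chicken builds GRCg6a and galGal6, with no order or role stated. The log2 fold changes and their standard errors in the authors' deposited tables come, per the file headers, from a DESeq2 comparison of each knockout with control. The p-values and adjusted p-values of the same deposited tables are the authors' own, per the file headers. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of overlapping genes and of near-identical copies, such as the W-linked and Z-linked forms of a gene, can be shared or lost. Symbols were taken from the deposited tables, which pair 13354 of 24356 listed identifiers with a symbol. Some symbols in these tables had been turned into dates, and none of those is named. The gene table at hand was of another assembly and held no matching identifiers, so no coordinates are printed.

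Library totals were 31.7, 30.8 and 27.8 M counts in control, 32.2, 32.0 and 30.0 M in LIN28A knockout and 30.8, 27.7 and 30.3 M in the libraries labelled LIN28B knockout. Of 24356 genes, 3859 had 0 counts in all libraries and 15475 passed the filter and were tested, 12343 of them with a symbol. The common biological coefficient of variation was 0.265. The floor of 3 counts per library covers counting error alone and not the spread between libraries.

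Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr at its defaults, a quasi-likelihood fit of all 9 libraries on group, and an F test of each contrast with Benjamini-Hochberg adjusted p under 0.05. The contrasts were LIN28A knockout against control, LIN28B knockout against control, and LIN28A knockout against LIN28B knockout. Log2 fold changes are given with a standard error from the F statistic, and CPM as TMM-scaled mean and SD over 3 libraries. Gene lists were tested with limma 3.58.1 (camera on voom values, preset correlation 0.01), adjusted over the lists with at least 5 tested members in each comparison. The 27 lists were germ cell identity, piRNA pathway, pluripotency, let-7 targets, miRNA processing, S phase, G2 and mitosis, p53 and apoptosis, FGF and ERK targets, activin and nodal signalling, BMP signalling, WNT signalling, insulin and IGF signalling, glycolysis, oxidative phosphorylation, ribosomal proteins, integrated stress response, interferon response, mesoderm and endoderm, ectoderm and neural, meiosis, extracellular matrix and adhesion, fibroblast markers, erythroid markers, leukocyte markers, endothelial markers and W chromosome genes. Of these 26 could be tested. Marker lists share members with other lists: fibroblast markers 14 of 20 tested members, endothelial markers 1 of 13, erythroid markers 0 of 8 and leukocyte markers 0 of 12. The medians of a list per library are medians over its members of log2 CPM minus the control mean.

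The groups, contrasts, tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule named LIN28A and LIN28B; the 6 largest rises and 6 largest falls among called genes with a symbol, an average log2 CPM of at least 3 and no overlap of CPM between the groups; up to 2 called members of each list; and DDX4, DAZL, PIWIL1, NANOG, POU5F3, PRDM1, MYC and CXCR4. For the knockouts against each other it named LIN28A, LIN28B and 4 genes each way. POU5F3 is not among the symbols of the tested genes. Other named genes were chosen after their values were seen, from the fit with the replicate block, the lists described, the deposited tables or the called genes.

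Replicate numbers carry no stated meaning in the labels. Whether they pair the libraries was checked before the fits were compared, by the correlation across genes of deviations from the group mean. The correlation of same-numbered libraries was 0.187, 0.149 and 0.281 between control and LIN28A knockout and 0.150, 0.212 and 0.347 between control and LIN28B knockout, all above 0.1, so these numbers were taken to pair the libraries and the fit with the replicate number as a block is given where it differs. Replicates 1 and 2 are not told apart by this check, since control replicate 1 with knockout replicate 2 gave 0.176 and 0.191. Control replicate 2 with knockout replicate 1 gave 0.175 and 0.141. Deviations from a group mean cancel out within the group, so the same-number correlations of a comparison are not separate evidence. The check bears only on replicate 3 against replicates 1 and 2. That part of the pairing comes from the data and not from the design. Matching replicates 1 and 2 by number in the block rests on the number alone.

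Alternatives were DESeq2 size factors in the same fit, DESeq2 1.42.0 itself, no filter, a filter of 5 CPM in 3 libraries, a fit of the compared groups alone, the replicate block, an estimated correlation and the rotation test fry for lists, and leaving out each library in turn. A term for replicate 3, a fit of replicates 1 and 2 alone and the newer quasi-likelihood of edgeR were added after seeing the data. The correlation of the knockout effects was set beside 50 simulated draws with no change in either knockout, since 3 control libraries cannot be divided between the comparisons. In each draw all 9 libraries, the control too, came from 1 mean per gene with the fitted dispersions. A further 50 draws used 1 mean per gene and replicate number. These simulations were made after the observed correlation was seen.

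The tests were tried on simulated data for LIN28A knockout against control over 15040 genes. The edgeR test recovered 54% of genes changed by a log2 fold change of 1 and 93% of those changed by 2, and called 6 of 14810 unchanged genes. DESeq2 recovered 73% and 98% and called 40 unchanged genes. The camera test found the 1 shifted list and called 0 of 25 others. The simulated genes were drawn independently, so this trial does not test camera on lists whose members are correlated.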

Results

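Poly(A) RNA was sequenced from chicken (Gallus gallus) primordial germ cells (PGCs), the embryonic cells that give rise to eggs and sperm. The series held 3 groups of 3 libraries each, labelled as cells with a control vector, as LIN28A knockout and as LIN28B knockout. These names stand for the labels, since the transcript of the targeted gene was not lower in the libraries labelled LIN28B knockout and was still at 72.8% and 76.2% of control in 2 of those labelled LIN28A knockout. LIN28A and LIN28B encode RNA-binding proteins known for blocking the maturation of let-7 microRNAs, and the series asked whether they are needed to keep PGCs. Total counts ran from 27.7 to 32.2 M per library over 24356 listed genes, of which 15475 were tested. A floor of 3 counts stood for 0.0931 to 0.108 CPM (counts scaled to library size), depending on the library. The 10 most abundant genes took 4.23% to 5.62% of the counts of a library.

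Replicates 1 and 2 of each group lay close together, and replicate 3 stood apart from both. Over 10151 genes with an average log2 CPM of at least 3, the root mean square log2 difference between replicates 1 and 2 was 0.141 in control, 0.137 in LIN28A knockout and 0.164 in the libraries labelled LIN28B knockout. Replicate 3 differed from replicates 1 and 2 by 0.365 and 0.384 in control, by 0.398 and 0.443 in the libraries labelled LIN28B knockout, and by 0.725 and 0.713 in LIN28A knockout. Over the same genes, the log2 differences from control in replicates 1 and 2 and those in replicate 3 correlated at r = 0.0541 for LIN28A knockout, with the same sign in 52.7%. For the libraries labelled LIN28B knockout these were r = 0.463 and 64.2%. Differences of LIN28A knockout over all 3 replicates thus average sets of libraries whose differences hardly correlated. Replicates 1 and 2 differed by more than the noise of counting (chi-square per degree of freedom 4.94 to 6.22), which does not tell separate cultures from separate preparations of 1 culture. The labels number them as replicates, and all 9 libraries were kept as such. Values with the replicate number as a block are given beside those of each knockout against control where the block changes a call or a count by more than 1.5 times. The data bear only on setting replicate 3 apart in this block. They do not show that replicates 1 and 2 match by number across groups. Genes said not to pass are those that edgeR did not call over all 9 libraries. Some fits leave out LIN28A knockout replicate 3, which keeps only the LIN28A knockout libraries at 72.8% and 76.2% of control LIN28A transcript. That library is in neither group of LIN28B knockout against control, where leaving it out can act only through the shared fit. Calls gained in these fits show dependence on that library and are no added support. Genes named from the fit with the block, and list members given as examples, were chosen after their values were seen.

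**Figure D1:**
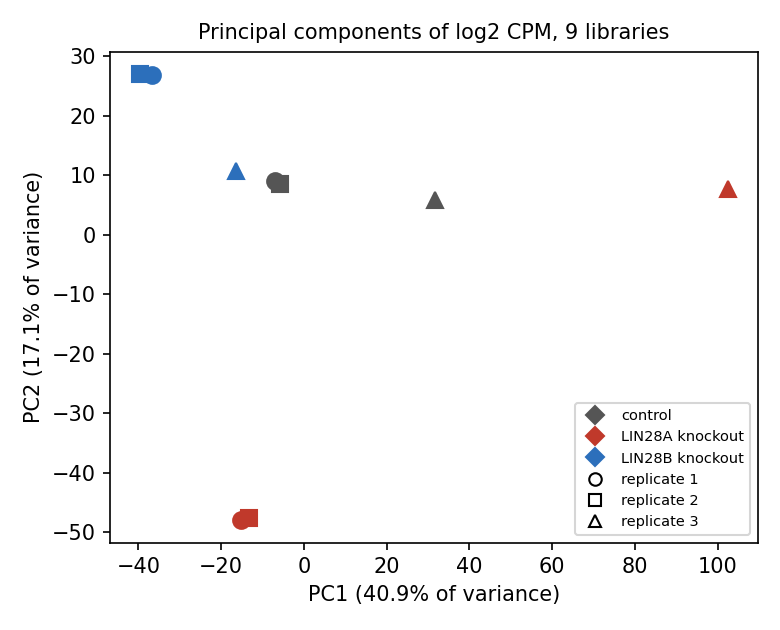
Principal components of log2 CPM for the 9 libraries, with 40.9% of the variance on the first axis and 17.1% on the second. LIN28A knockout replicate 3 lay apart from replicates 1 and 2 of its group.

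LIN28A (ENSGALG00000036022) transcripts averaged 183 ± 53.5 CPM (SD, n = 3) in control and 81.3 ± 55.2 CPM (n = 3) in LIN28A knockout. The log2 fold change of LIN28A was −1.17 ± 0.53 (SE), which did not pass the test (edgeR adjusted p = 0.479). The 3 LIN28A knockout libraries were unlike each other: LIN28A stood at 117, 109 and 17.7 CPM in replicates 1, 2 and 3, or 72.8%, 76.2% and 7.28% of the control library with the same number. LIN28B (ENSGALG00000026761) was not lower in the libraries labelled LIN28B knockout, at 55.0 ± 4.65 CPM (n = 3) against 53.2 ± 8.30 CPM (n = 3) in control, with a log2 fold change of 0.05 ± 0.14 (edgeR adjusted p = 0.929). Single libraries labelled LIN28B knockout held 55.0, 59.6 and 50.3 CPM of LIN28B. In LIN28A knockout, LIN28B was at 40.0 ± 1.89 CPM (n = 3), a log2 fold change of −0.41 ± 0.14 (edgeR adjusted p = 0.327). LIN28A in the libraries labelled LIN28B knockout was at 198 ± 38.2 CPM (n = 3), a log2 fold change of 0.12 ± 0.53 (edgeR adjusted p = 0.958). The labels do not say how the genes were disrupted, and a small edit that ends the protein can leave the transcript count unchanged, so transcript amounts neither prove nor rule out loss of LIN28B.

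**Figure D2:**
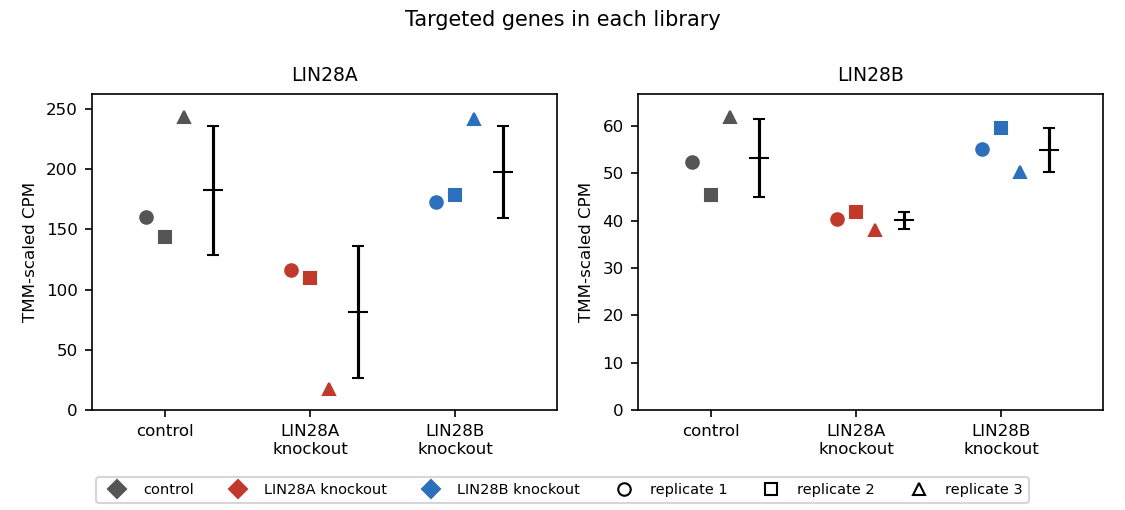
CPM of LIN28A and LIN28B in each library. LIN28A was lowest in LIN28A knockout replicate 3, and LIN28B was not lower in the libraries labelled LIN28B knockout.

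LIN28A knockout was compared with control to find the transcripts that differ when LIN28A is targeted, with the caution that replicates 1 and 2 kept most of the LIN28A transcript. Oxidative phosphorylation transcripts, which encode the mitochondrial respiratory chain and ATP synthase, fell as a group. Of 69 tested members 63 lay below control, with a median log2 fold change of −0.23 (limma camera adjusted p = 2.00e-15; adjusted p = 0.212 with an estimated correlation). The list median was below 0 in all LIN28A knockout libraries (−0.20, −0.29 and −0.17, against 0.02, 0.04 and −0.06 in control). ATP5F1AW (ENSGALG00000043758), the W-linked copy of the ATP synthase alpha subunit, fell from 87.9 ± 1.5 CPM (SD, n = 3) to 40.2 ± 0.26 CPM (n = 3), a log2 fold change of −1.13 ± 0.10 (SE; edgeR adjusted p = 0.0112). It was the 1 member of the oxidative phosphorylation list called over all genes, and the 1 member called adjusted over the list alone. Other members were lower without passing, such as ATP5G1 at −0.50 ± 0.13 (edgeR adjusted p = 0.220) and COX7B at −0.46 ± 0.12 (edgeR adjusted p = 0.214). Reads of ATP5F1AW can be shared with its near-identical Z-linked copy ATP5F1AZ, which was at 659 ± 20.4 CPM (n = 3) in control and 596 ± 63.1 CPM (n = 3) in LIN28A knockout.

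Genes of extracellular matrix and adhesion rose as a group in LIN28A knockout: 48 of 65 tested members lay above control, with a median log2 fold change of 0.31 and a mean of 0.60 (camera adjusted p = 4.67e-05; adjusted p = 0.791 with an estimated correlation). Over all genes edgeR called 0 members, against 24 higher and 2 lower at an unadjusted p under 0.05, 9 higher by DESeq2, and 12 higher and 1 lower adjusted over the list alone. The authors' deposited table had 10 of them higher. With the replicate block 2 members were called higher: the fibrillar collagen COL5A2 at 0.88 ± 0.10 (edgeR adjusted p = 0.0388 with the block, 0.195 without it) and the microfibril gene FBN1 at 0.79 ± 0.09 (edgeR adjusted p = 0.0388 with the block, 0.152 without it). SERPINH1, a chaperone of collagen folding outside the list, rose in the same blocked fit by 0.81 ± 0.08 (edgeR adjusted p = 0.0244 with the block, 0.170 without it), from 183 ± 29.9 to 320 ± 51.8 CPM (SD, n = 3 each). COL14A1 likewise rose by 1.35 ± 0.13 (edgeR adjusted p = 0.0289 with the block, 0.126 without it). Collagen genes with larger differences did not pass, such as COL5A1 at 2.02 ± 0.29 (edgeR adjusted p = 0.0925) and COL6A1 at 2.38 ± 0.47 (edgeR adjusted p = 0.126). Both passed edgeR without LIN28A knockout replicate 3 (adjusted p = 4.45e-05 and 4.24e-05). Both also passed DESeq2 on all libraries (adjusted p = 3.17e-08 and 4.95e-05) and the threshold in the authors' deposited table (2.00e-06 and 4.33e-04). FBN1 and COL14A1 also passed edgeR without that library (adjusted p = 0.00707 and 0.0213). The difference of the list was largest in replicates 1 and 2, where the matrix list median was 0.52 and 0.44, and small in replicate 3 (−0.07), against 0.11, 0.06 and −0.15 in control, while SERPINH1 and COL5A2 were higher in replicate 3 as well. Fibroblast markers, with 11 of 20 tested members shared with the matrix list, stood at 0.39, 0.30 and −0.37 in the same libraries, against 0.19, 0.10 and −0.25 in control, and did not pass (camera adjusted p = 0.523). Without LIN28A knockout replicate 3 the fibroblast markers did pass, higher (camera adjusted p = 2.30e-05), and the matrix list reached 1.17e-14. COL1A1, the main collagen of fibroblasts, was at 590, 517 and 73.3 CPM in LIN28A knockout and 86.9 ± 32.5 CPM (n = 3) in control. COL1A1 was called by edgeR without LIN28A knockout replicate 3 (adjusted p = 0.00411), and not by DESeq2 on all libraries (adjusted p = 0.0870).

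Cell cycle lists were lower in LIN28A knockout. S phase genes, which act in DNA replication, were below control in 32 of 41 tested members, with a median of −0.17 (camera adjusted p = 1.72e-04; adjusted p = 0.791 with an estimated correlation) and 1 member lower adjusted over the list alone. Genes of G2 and mitosis were below control in 30 of 41 tested members, with a median of −0.11 (camera adjusted p = 0.0165; adjusted p = 0.791 with an estimated correlation). Their list medians were −0.20, −0.18 and 0.02 in the LIN28A knockout libraries, against −0.10, −0.09 and 0.17 in the control libraries of the same numbers. The call of G2 and mitosis was lost without control replicate 3 (adjusted p = 0.50), LIN28A knockout replicate 1 (adjusted p = 0.151) or LIN28A knockout replicate 2 (adjusted p = 0.106). Over all genes edgeR called 0 members of S phase and of G2 and mitosis, against 5 and 4 lower at an unadjusted p under 0.05, and DESeq2 called 1 lower in S phase.

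Stress lists were higher in LIN28A knockout. The integrated stress response is the ATF4 programme, set off by shortage of amino acids among other stresses. This list was above control in 26 of 29 tested members, with a median of 0.24 (camera adjusted p = 0.00259, and 0.791 with an estimated correlation). Its list median was 0.05, 0.01 and 0.68 in replicates 1, 2 and 3, against −0.08, −0.04 and 0.14 in control. The call was lost without LIN28A knockout replicate 3 (adjusted p = 0.916) and held with replicates 1 and 2 only of every group (integrated stress response in LIN28A knockout, camera adjusted p = 0.0273). Over all genes edgeR called 0 members of this list, against 2 higher and 1 lower at an unadjusted p under 0.05 and 1 higher by DESeq2. Genes of p53 and apoptosis were above control in 21 of 37 tested members, with a median of 0.15 (camera adjusted p = 0.0388; adjusted p = 0.533 with an estimated correlation). Over all genes edgeR called 0 of them, against 4 higher and 1 lower at an unadjusted p under 0.05 and the same counts by DESeq2, and 4 higher and 1 lower adjusted over the list alone. The cell cycle inhibitor CDKN1A went from 2.75 ± 1.53 CPM (n = 3) to 11.1 ± 0.60 CPM (n = 3), a log2 fold change of 2.02 ± 0.37 that did not pass (edgeR adjusted p = 0.126). The death receptor FAS was at 1.86 ± 0.37 (edgeR adjusted p = 0.126). CDKN1A and FAS passed edgeR without LIN28A knockout replicate 3 (adjusted p = 0.0255 and 0.0389). They passed DESeq2 on all libraries as well (adjusted p = 3.46e-05 and 2.52e-04). The p53 call was lost with the replicate block (adjusted p = 0.0986), with a stricter filter (adjusted p = 0.117), and without control replicate 1 (adjusted p = 0.0713), control replicate 2 (adjusted p = 0.0823) or LIN28A knockout replicate 3 (adjusted p = 0.309). It was lost with replicates 1 and 2 only as well (adjusted p = 0.0950).

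Germ cell genes did not shift one way as a group in LIN28A knockout. The germ cell identity list, with 19 tested members, had a median of 0.10 (camera adjusted p = 0.535), with 3 members higher and 3 lower adjusted over the list alone. The mixed test of fry, which asks whether members change in either direction, did pass (adjusted p = 4.23e-05). It also passed for oxidative phosphorylation (1.84e-05) and p53 and apoptosis (1.38e-04). CXCR4, the receptor that guides migrating PGCs, went from 35.0 ± 9.20 CPM (n = 3) to 12.5 ± 2.96 CPM (n = 3), a log2 fold change of −1.48 ± 0.30 that did not pass (edgeR adjusted p = 0.126). Under the block CXCR4 fell by 1.47 ± 0.12 (edgeR adjusted p = 0.0159 with the block). The germ cell translation regulator DAZL was at −0.45 ± 0.10 (edgeR adjusted p = 0.161), the RNA helicase DDX4 at 0.20 ± 0.17 (edgeR adjusted p = 0.732) and the piRNA-binding gene PIWIL1 at −0.21 ± 0.14 (edgeR adjusted p = 0.646). Pluripotency gene NANOG was at −0.18 ± 0.18 (edgeR adjusted p = 0.772), PRDM1, a repressor of somatic genes, at 0.10 ± 0.26 (edgeR adjusted p = 0.927) and MYC, a growth gene and let-7 target, at 0.95 ± 0.37 (edgeR adjusted p = 0.412). CXCR4 and DAZL passed DESeq2 (adjusted p = 4.40e-04 and 0.00855), and MYC did not (adjusted p = 0.233). DAZL and MYC were called by edgeR without LIN28A knockout replicate 3 (adjusted p = 0.0250 and 0.0327). The let-7 targets, which LIN28 loss would lower if let-7 rose, had a median of −0.02 over 53 tested members (camera adjusted p = 0.400), with 2 lower adjusted over the list alone.

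Further genes fell in LIN28A knockout in the fit with the replicate block. SLIT1, a secreted guidance molecule, fell from 429 ± 47.1 to 162 ± 36.3 CPM (n = 3 each), a log2 fold change of −1.43 ± 0.09 (edgeR adjusted p = 0.00885 with the block, 0.0687 without it). The mesendoderm factor EOMES fell by 0.88 ± 0.09 (edgeR adjusted p = 0.0289 with the block, 0.126 without it) and the neuropeptide gene NTS fell by 1.51 ± 0.14 (edgeR adjusted p = 0.0244 with the block, 0.214 without it). ICA1, a vesicle gene, rose by 0.85 ± 0.09 (edgeR adjusted p = 0.0388 with the block, 0.0655 without it) and MAP7, a microtubule-binding gene, by 0.98 ± 0.11 (edgeR adjusted p = 0.0453 with the block, 0.230 without it). SLIT1, EOMES and ICA1 passed edgeR with no block when LIN28A knockout replicate 3 was left out (adjusted p = 0.00413, 0.0243 and 0.00180).

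In numbers, edgeR called 1 gene in LIN28A knockout against control, 0 higher and 1 lower, with an absolute log2 fold change of at least 1, against 1643 at an unadjusted p under 0.05. Under the block edgeR called 13 (7 higher and 6 lower), and DESeq2 called 381 (203 higher and 178 lower). Without LIN28A knockout replicate 3 edgeR called 453, and the call of ATP5F1AW was lost without control replicate 1, 2 or 3 (edgeR adjusted p = 0.143, 0.123 and 0.0908), LIN28A knockout replicate 1 or 2 (edgeR adjusted p = 0.142 and 0.125) or LIN28B knockout replicate 2 (edgeR adjusted p = 0.0573).

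LIN28B knockout was compared with control for the same purpose, with the caution that LIN28B transcript was not lower in the libraries labelled LIN28B knockout. The sample descriptions of these libraries also name the result table of LIN28A knockout and not that of LIN28B knockout. Other measures do not settle the labels. DESeq2 on these libraries and control gave the authors' deposited table for LIN28B knockout to within a median log2 fold change of 2.3e-05. This would hold whether or not the labels are right. LIN28A stood at 72.8%, 76.2% and 7.28% of the same-numbered control in LIN28A knockout, a fall that did not pass edgeR. In the libraries labelled LIN28B knockout LIN28A averaged 198 CPM, against 183 in control. LIN28B averaged lowest in LIN28A knockout. No measure here shows loss of LIN28B. The integrated stress response fell as a group: 25 of 29 tested members lay below control, with a median log2 fold change of −0.56 (camera adjusted p = 6.37e-13; adjusted p = 0.509 with an estimated correlation). Its list median was below 0 in all libraries labelled LIN28B knockout (−0.54, −0.67 and −0.28, against −0.08, −0.04 and 0.14 in control). Over all genes edgeR called 0 members, against 19 lower at an unadjusted p under 0.05, 5 lower by DESeq2, 14 lower in the authors' deposited table and 16 lower adjusted over the list alone. With the replicate block 2 members were called lower, the amino acid transporter SLC7A5 at −0.92 ± 0.09 (edgeR adjusted p = 0.0318 with the block, 0.502 without it, DESeq2 adjusted p = 0.174) and the secreted hormone gene STC2 at −1.36 ± 0.16 (edgeR adjusted p = 0.0422 with the block, 0.457 without it). SLC7A5 went from 292 ± 100 to 155 ± 55.1 CPM and STC2 from 126 ± 31.2 to 52.5 ± 28.4 CPM (SD, n = 3 each). Members that did not pass over all genes included the cystine transporter SLC7A11 at −2.65 ± 0.64 (edgeR adjusted p = 0.393), the glutathione-degrading CHAC1 at −1.96 ± 0.61 (edgeR adjusted p = 0.476), the asparagine synthetase ASNS at −1.01 ± 0.34 (edgeR adjusted p = 0.488) and ATF4 itself at −0.56 ± 0.16 (edgeR adjusted p = 0.457). PYCR1, of proline synthesis and outside the list, fell by 0.82 ± 0.10 (edgeR adjusted p = 0.0422 with the block, 0.348 without it). SLC7A11 and PYCR1 passed edgeR with no block when LIN28A knockout replicate 3 was left out (adjusted p = 0.0220 and 0.0493), and both passed DESeq2 on all libraries (adjusted p = 0.00591 and 0.0138). The library left out is in neither group compared here.

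Glycolysis genes fell as a group in the libraries labelled LIN28B knockout: 19 of 26 tested members lay below control, with a median of −0.19 (camera adjusted p = 9.01e-05; adjusted p = 0.509 with an estimated correlation). PFKFB3 (ENSGALG00000040369), whose product speeds glycolysis, fell from 49.0 ± 3.11 CPM (n = 3) to 23.2 ± 0.86 CPM (n = 3), a log2 fold change of −1.08 ± 0.11 (edgeR adjusted p = 0.0230). It was the 1 member of the glycolysis list called over all genes, and 2 were lower adjusted over the list alone. The glucose transporter SLC2A1 at −0.50 ± 0.13 (edgeR adjusted p = 0.410) and the hexokinase HK2 at −0.50 ± 0.20 (edgeR adjusted p = 0.535) did not pass. Oxidative phosphorylation was lower too, with 56 of 69 tested members below control and a median of −0.07 (camera adjusted p = 0.00291; adjusted p = 0.629 with an estimated correlation), a call lost without control replicate 2 (adjusted p = 0.0861). BNIP3L, a gene for removal of mitochondria, fell by 0.76 ± 0.09 with the block (edgeR adjusted p = 0.0422) and did not pass without it (edgeR adjusted p = 0.559, DESeq2 adjusted p = 0.336, 0.106 in the authors' deposited table). The gene ENSGALG00000041459, which carries no symbol in the tables used here, fell from 90.5 ± 4.56 CPM (n = 3) to 24.0 ± 1.13 CPM (n = 3), a log2 fold change of −1.92 ± 0.20 (edgeR adjusted p = 0.0230).

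Cell cycle lists were lower in the libraries labelled LIN28B knockout as well. Genes of G2 and mitosis lay below control in 39 of 41 tested members, with a median of −0.33 (camera adjusted p = 1.21e-11; adjusted p = 0.629 with an estimated correlation). The medians were −0.56, −0.63 and 0.08 in these libraries and −0.10, −0.09 and 0.17 in control. Mitotic genes such as CDC20 at −0.60 ± 0.17 (edgeR adjusted p = 0.468) and PLK1 at −0.53 ± 0.18 (edgeR adjusted p = 0.496) did not pass over all genes. S phase genes lay below control in 32 of 41 tested members, with a median of −0.10 (camera adjusted p = 0.00196; adjusted p = 0.629 with an estimated correlation), a call lost without LIN28B knockout replicate 2 (adjusted p = 0.0779). Over all genes edgeR called 0 members of G2 and mitosis and of S phase, against 7 and 4 lower at an unadjusted p under 0.05, and DESeq2 called 1 lower in S phase.

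Developmental signalling lists were higher in the libraries labelled LIN28B knockout. Mesoderm and endoderm genes lay above control in 20 of 32 tested members, with a median of 0.38 (camera adjusted p = 0.00199; adjusted p = 0.629 with an estimated correlation), and 2 were higher and 1 lower adjusted over the list alone. TBX6, a factor of paraxial mesoderm, rose from 165 ± 23.4 to 308 ± 52.1 CPM (n = 3 each), by 0.89 ± 0.09 (edgeR adjusted p = 0.0318 with the block, 0.367 without it). TBX6 passed with no block when LIN28A knockout replicate 3 was left out (edgeR adjusted p = 0.0285). The list median was 0.73, 0.47 and 0.15 in these libraries and 0.39, 0.18 and −0.72 in control, and the call was lost without control replicate 3 (adjusted p = 0.309) and with replicates 1 and 2 only (adjusted p = 0.127). Endothelial markers, with 13 tested members, moved alike at 1.11, 0.72 and 0.24 against 0.51, 0.23 and −0.64, and passed with the replicate block (camera adjusted p = 0.0256) but not without it (camera adjusted p = 0.0948). WNT signalling genes lay above control in 32 of 43 tested members, with a median of 0.26 (camera adjusted p = 0.00338; adjusted p = 0.509 with an estimated correlation) and list medians of 0.31, 0.32 and 0.14, against 0.05, 0.02 and −0.01 in control. The WNT ligand-booster RSPO2 was at 0.67 ± 0.19 (edgeR adjusted p = 0.457) and the nuclear partner LEF1 at 0.41 ± 0.14 (edgeR adjusted p = 0.502). Activin and nodal signalling, the pathway that feeds PGC growth in culture, lay above control in 19 of 26 tested members, with a median of 0.27 (camera adjusted p = 0.0389; adjusted p = 0.629 with an estimated correlation). That call was lost without a filter (adjusted p = 0.0638), with a stricter filter (adjusted p = 0.172), and without control replicate 2 (adjusted p = 0.0861), control replicate 3 (adjusted p = 0.0807), LIN28B knockout replicate 1 (adjusted p = 0.167) or LIN28B knockout replicate 2 (adjusted p = 0.271). With the replicate block FGF and ERK targets (camera adjusted p = 0.0208, 0.0709 without it) and interferon response (camera adjusted p = 0.0490, 0.0948 without it) were higher as well. With an estimated correlation and no block, camera gave adjusted p = 0.751 for FGF and ERK targets. Interferon response and endothelial markers gave 0.629 each in that setting.

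Matrix genes went the other way from LIN28A knockout in single cases. SERPINH1 fell by 1.06 ± 0.08 (edgeR adjusted p = 0.0167 with the block, 0.161 without it) to 87.9 ± 19.0 CPM (n = 3), and COL5A2 fell by 0.93 ± 0.10 (edgeR adjusted p = 0.0318 with the block, 0.348 without it). SERPINH1 passed with no block when LIN28A knockout replicate 3 was left out (edgeR adjusted p = 0.0256). The extracellular matrix and adhesion list as a whole had a median of 0.12 in the libraries labelled LIN28B knockout and did not pass (camera adjusted p = 0.200), with 7 higher and 6 lower in the authors' deposited table. The germ cell lists did not pass: germ cell identity had a median of 0.07 (camera adjusted p = 0.588), with 2 members higher adjusted over the list alone and the mixed test of fry not passed (adjusted p = 0.181). NANOG was at 0.42 ± 0.18 (edgeR adjusted p = 0.560), DAZL at −0.23 ± 0.10 (edgeR adjusted p = 0.560), DDX4 at 0.18 ± 0.17 (edgeR adjusted p = 0.773) and PIWIL1 at 0.24 ± 0.14 (edgeR adjusted p = 0.638). PRDM1 was at 0.50 ± 0.26 (edgeR adjusted p = 0.603), CXCR4 at −0.12 ± 0.29 (edgeR adjusted p = 0.919) and MYC at −0.07 ± 0.38 (edgeR adjusted p = 0.965).

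Genes called in the libraries labelled LIN28B knockout against control numbered 2 by edgeR, 0 higher and 2 lower, both with an absolute log2 fold change of at least 1, against 1372 at an unadjusted p under 0.05. Under the block edgeR called 24 (8 higher and 16 lower), and DESeq2 called 158 (69 higher and 89 lower). Among the lower genes with the block were the factors OTX1 at −1.63 ± 0.20 (edgeR adjusted p = 0.0422 with the block, 0.410 without it) and JDP2 at −1.64 ± 0.15 (edgeR adjusted p = 0.0318 with the block, 0.348 without it). ZEB1 at −0.91 ± 0.11 passed with the block alone (edgeR adjusted p = 0.0422, 0.560 without it, DESeq2 adjusted p = 0.320). OTX1 passed with no block when LIN28A knockout replicate 3 was left out (edgeR adjusted p = 0.0462). Without LIN28A knockout replicate 3 edgeR called 166 and without LIN28B knockout replicate 3 it called 21. Leaving out LIN28A knockout replicate 2 left 1 call. PFKFB3 was lost without control replicate 1, 2 or 3 (edgeR adjusted p = 0.183, 0.215 and 0.0764), LIN28A knockout replicate 1 or 2 (edgeR adjusted p = 0.0711 and 0.0769) or LIN28B knockout replicate 1 or 2 (edgeR adjusted p = 0.254 and 0.307). ENSGALG00000041459 was lost without the same libraries except LIN28A knockout replicate 2 (edgeR adjusted p = 0.0711 to 0.307).

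The knockouts were also compared with each other, with the same caution on the libraries labelled LIN28B knockout. This tests whether the knockouts differ, and does not say which group moved or which gene was the cause. The integrated stress response was higher in LIN28A knockout: 26 of 29 tested members, with a median of 0.87 (camera adjusted p = 8.51e-15; adjusted p = 0.488 with an estimated correlation), and 23 higher adjusted over the list alone. The 1 member called over all genes was HERPUD1, of protein quality control, at 0.87 ± 0.12 (edgeR adjusted p = 0.0254), against 23 at an unadjusted p under 0.05 and 19 by DESeq2. HERPUD1 was lost without control replicate 1 or 2 or replicate 1 or 2 of either knockout (edgeR adjusted p = 0.0682 to 0.138). It was also lost with only the 2 groups compared (0.138). Matrix genes with the largest differences were COL6A2 at 4.64 ± 0.77 (edgeR adjusted p = 0.0399), COL6A1 at 3.10 ± 0.48 (edgeR adjusted p = 0.0342) and COL5A1 at 2.35 ± 0.29 (edgeR adjusted p = 0.0152). SOX9, a cartilage factor and no matrix gene, was higher by 2.81 ± 0.47 (edgeR adjusted p = 0.0399). VCAN, a matrix proteoglycan outside the list, was lower in LIN28A knockout at −1.47 ± 0.22 (edgeR adjusted p = 0.0329). COL5A1 averaged 109 ± 45.4 CPM in LIN28A knockout and 21.4 ± 2.18 CPM in the libraries labelled LIN28B knockout (n = 3 each). COL5A1 was lost without LIN28B knockout replicate 1 or 2 (edgeR adjusted p = 0.13 and 0.118), LIN28A knockout replicate 1 or 2 (0.0743 and 0.0655) or control replicate 1 (0.0502), and with only the 2 groups compared (0.121). COL6A1, COL6A2 and SOX9 were lost without any single control library, LIN28A knockout replicate 1 or 2, or LIN28B knockout replicate 1 or 2 (edgeR adjusted p = 0.0605 to 0.242), and with only the 2 groups compared (0.154, 0.160 and 0.160). COL6A1 and COL6A2 were also lost without LIN28B knockout replicate 3 (edgeR adjusted p = 0.0525 and 0.0556). VCAN was lost without control replicate 1 or 2, LIN28A knockout replicate 1 or 2, or LIN28B knockout replicate 1 or 2 (edgeR adjusted p = 0.0672 to 0.183), and with only the 2 groups compared (0.121). SERPINH1 was higher by 1.87 ± 0.19 (edgeR adjusted p = 0.00706) and COL5A2 by 1.81 ± 0.21 (edgeR adjusted p = 0.0138). SERPINH1 was lost without LIN28B knockout replicate 1 or 2 (edgeR adjusted p = 0.0684 and 0.0678). COL5A2 was lost without the same libraries (edgeR adjusted p = 0.124 and 0.105) and without LIN28A knockout replicate 1 or 2 (edgeR adjusted p = 0.0524 and 0.0542). Of the extracellular matrix list 4 members were called higher over all genes and 13 higher and 1 lower adjusted over the list alone. The list itself had a median of 0.10 and a mean of 0.52 and did not pass (camera adjusted p = 0.0680). It passed, higher, without LIN28A knockout replicate 3 (camera adjusted p = 1.10e-08), LIN28B knockout replicate 1 (0.0295) or LIN28B knockout replicate 2 (0.0161). Fibroblast markers had 2 members called higher, a median of −0.09 against a mean of 0.59, and did not pass (camera adjusted p = 0.591, but 3.46e-05 without LIN28A knockout replicate 3).

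Genes of p53 and apoptosis were higher in LIN28A knockout than in the libraries labelled LIN28B knockout, with a median of 0.14 over 37 tested members (camera adjusted p = 0.0386; adjusted p = 0.488 with an estimated correlation). Of these 3 were called higher over all genes, and 6 higher and 1 lower adjusted over the list alone. CDKN1A was higher by 2.56 ± 0.38 (edgeR adjusted p = 0.0286), the death receptor TNFRSF10B by 2.14 ± 0.37 (edgeR adjusted p = 0.0434) and the BCL2-family gene PMAIP1 by 2.21 ± 0.38 (edgeR adjusted p = 0.0434). TNFRSF10B and PMAIP1 were lost without any single control library or replicate 1 or 2 of either knockout (edgeR adjusted p = 0.0570 to 0.248). They were also lost with only the 2 groups compared (0.151 each), and PMAIP1 without LIN28B knockout replicate 3 (0.0528). CDKN1A was lost without control replicate 1 or without replicate 1 or 2 of either knockout (0.0704 to 0.173). The call of the p53 list was lost with the replicate block (adjusted p = 0.0889), with the stricter filter (adjusted p = 0.298), without LIN28A knockout replicate 3 (adjusted p = 0.164) and without LIN28B knockout replicate 3 (adjusted p = 0.118). With replicates 1 and 2 only the p53 list (adjusted p = 0.411) and glycolysis (adjusted p = 0.194) were lost. Glycolysis was higher with a median of 0.21 over 26 tested members (camera adjusted p = 0.0151; adjusted p = 0.488 with an estimated correlation). Its 1 member called over all genes was PFKFB3 at 1.20 ± 0.11 (edgeR adjusted p = 0.00706), and 6 were higher adjusted over the list alone. Glycolysis was lost with the replicate block (adjusted p = 0.0683) and without LIN28A knockout replicate 3 (adjusted p = 0.0568) or LIN28B knockout replicate 3 (adjusted p = 0.0877). G2 and mitosis was higher with a median of 0.19 over 41 tested members (camera adjusted p = 0.00258; adjusted p = 0.820 with an estimated correlation), and was lost without LIN28A knockout replicate 3 (adjusted p = 0.0978), LIN28B knockout replicate 1 (adjusted p = 0.0829) or LIN28B knockout replicate 2 (adjusted p = 0.220).

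Lower in LIN28A knockout than in the libraries labelled LIN28B knockout was oxidative phosphorylation, with a median of −0.17 over 69 tested members (camera adjusted p = 1.08e-04; adjusted p = 0.488 with an estimated correlation). WNT signalling was lower with a median of −0.30 over 43 tested members (camera adjusted p = 0.00586; adjusted p = 0.488 with an estimated correlation). ATP5F1AW was lower at −0.84 ± 0.10 (edgeR adjusted p = 0.0152). Mesoderm and endoderm genes were lower with a median of −0.79 over 32 tested members (camera adjusted p = 0.00247; adjusted p = 0.753 with an estimated correlation), with 3 higher and 9 lower adjusted over the list alone. EOMES was called over all genes at −1.06 ± 0.15 (edgeR adjusted p = 0.0254). The call of the list was lost without LIN28A knockout replicate 3 (adjusted p = 0.0978). Pluripotency genes were lower with a median of −0.36 over 20 tested members (camera adjusted p = 0.0151; adjusted p = 0.488 with an estimated correlation), 6 of them adjusted over the list alone. This was lost without LIN28A knockout replicate 3 (adjusted p = 0.0568). Activin and nodal signalling was lower with a median of −0.21 over 26 tested members (camera adjusted p = 0.0379; adjusted p = 0.790 with an estimated correlation). It was lost without LIN28A knockout replicate 3 (adjusted p = 0.200), LIN28B knockout replicate 1 (adjusted p = 0.110) or LIN28B knockout replicate 2 (adjusted p = 0.220). It was also lost without control replicate 1 (0.0586), control replicate 2 (0.0655) or LIN28A knockout replicate 1 (0.0632), and with no filter on low counts (0.0524). Single genes lower in LIN28A knockout were ZBBX at −2.72 ± 0.45 (edgeR adjusted p = 0.0399) and CCDC141, a gene of neuronal migration, at −2.31 ± 0.25 (edgeR adjusted p = 0.00935). Others were the protease receptor F2RL1 at −2.29 ± 0.35 (edgeR adjusted p = 0.0319), the peptide hormone gene APELA at −1.56 ± 0.27 (edgeR adjusted p = 0.0434) and SLIT1 at −1.52 ± 0.19 (edgeR adjusted p = 0.0152). With only the 2 groups compared, edgeR no longer called ZBBX (adjusted p = 0.121), CCDC141 (0.0829), F2RL1 (0.140), APELA (0.181), SLIT1 (0.117), ATP5F1AW (0.121) or EOMES (0.0940). APELA was also lost without any single library except LIN28A knockout replicate 3 (edgeR adjusted p = 0.0522 to 0.242). LIN28A was at −1.28 ± 0.53 (edgeR adjusted p = 0.253) and LIN28B at −0.46 ± 0.14 (edgeR adjusted p = 0.147).

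Between the knockouts edgeR called 80 genes, 58 higher and 22 lower in LIN28A knockout and 55 with an absolute log2 fold change of at least 1, against 2779 at an unadjusted p under 0.05. DESeq2 called 1018. Leaving out LIN28B knockout replicate 1 or 2 left 0 calls by edgeR, so none of the 80 calls held in every fit. Leaving out LIN28A knockout replicate 1 or 2 left 5 and 4, and control replicate 1, 2 or 3 left 9, 17 and 44. Without LIN28A knockout replicate 3 the count was 474, and without LIN28B knockout replicate 3 it was 230.

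**Figure D3:**
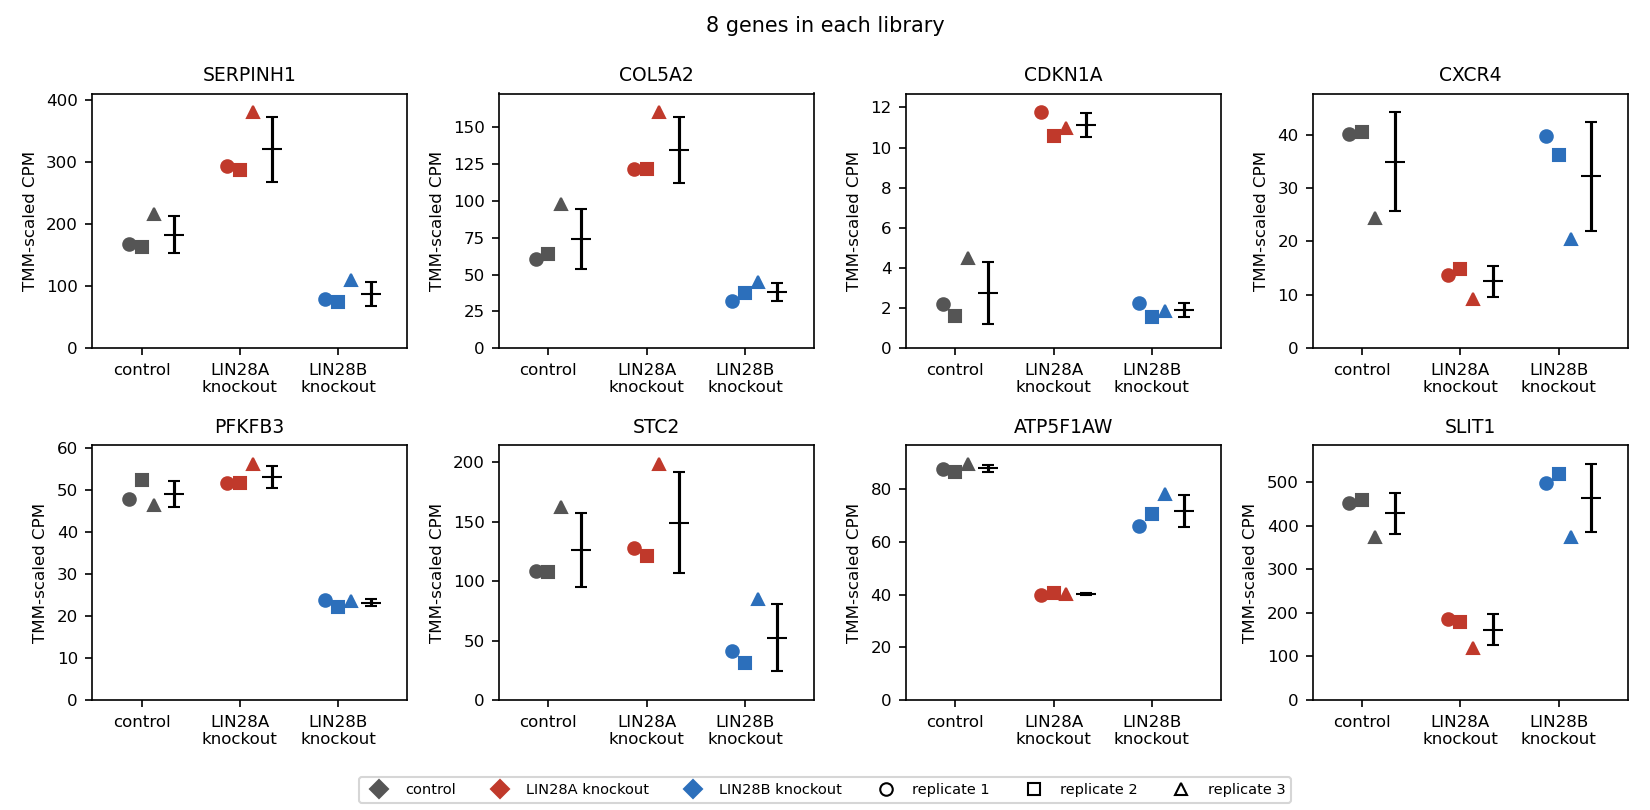
CPM of 8 genes in each library, with the mean and SD of each group. SERPINH1 and COL5A2 stood highest in LIN28A knockout and lowest in the libraries labelled LIN28B knockout, and ATP5F1AW was low in all LIN28A knockout libraries.

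**Figure D4:**
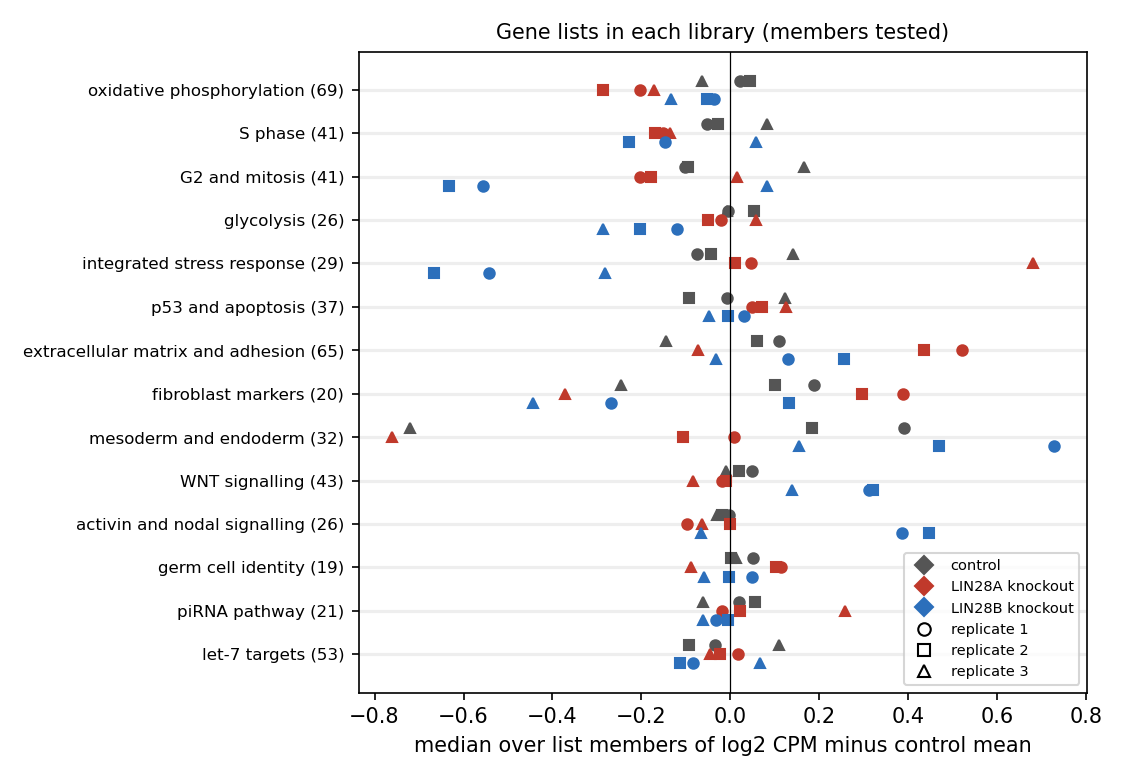
Median over list members of log2 CPM minus the control mean, for each library. The integrated stress response lay below 0 in all libraries labelled LIN28B knockout and far above 0 only in LIN28A knockout replicate 3.

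Effects of the knockouts against the shared control correlated at r = 0.190 over all tested genes. Simulated data with no change in either knockout and a shared control gave 0.501 ± 0.0124 (SD, 50 draws). The covariance was 0.0541, against 0.0898 in the simulation and 0.0811 in a simulation that kept the pattern of the replicate numbers. The correlation thus lay below that of unchanged groups with a shared control. Changes particular to 1 knockout also lower it, and the simulated spread came from all 9 libraries, LIN28A knockout replicate 3 among them. The comparison therefore neither shows nor excludes an effect shared by the knockouts. Of all tested genes 54.2% had the same sign, against 66.7% in the simulation. With 1 and 2 genes called by edgeR, the overlap of 0 genes (1.3e-04 for independent lists) says nothing on a shared effect.

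The authors' deposited table for LIN28A knockout had 301 genes under an adjusted p of 0.05, 185 higher and 116 lower, and the authors' deposited table for LIN28B knockout had 682, 342 higher and 340 lower. In the authors' deposited table ATP5F1AW had an adjusted p of 1.17e-22, and in that for LIN28B knockout PFKFB3 had 2.09e-15. Genes called by edgeR here and past the authors' threshold numbered 1 and 2. DESeq2 run on the deposited counts of the 2 groups compared differed from the authors' deposited table by a median log2 fold change of 2.2e-05 and 2.3e-05. That run called 261 and 650 genes, 261 and 641 of them also called in the authors' deposited table, while DESeq2 on all 9 libraries called 381 and 158. That the same software was run on the same counts means this is no second test. LIN28A in the authors' deposited table was at −1.16 with an adjusted p of 0.665.

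Most germ cell, microRNA and marker lists passed in neither knockout against control, with camera adjusted p given here for LIN28A knockout and then for LIN28B knockout. The piRNA pathway gave 0.269 and 0.462, meiosis 0.622 and 0.200, let-7 targets 0.400 and 0.789 and miRNA processing 0.303 and 0.605. Pluripotency gave 0.0732 (0.0487, lower, with the replicate block) and 0.143, ectoderm and neural genes 0.112 (0.0318, lower, with the replicate block) and 0.137, BMP signalling 0.523 and 0.322, and insulin and IGF signalling 0.436 and 0.605. Ribosomal proteins gave 0.0509 (0.0487, lower, with the replicate block) and 0.834, erythroid markers 0.438 and 0.605, leukocyte markers 0.257 and 0.835, and fibroblast markers 0.523 and 0.605. In LIN28A knockout alone FGF and ERK targets gave 0.970, activin and nodal signalling 0.523, WNT signalling 0.401, glycolysis 0.673, interferon response 0.112, mesoderm and endoderm 0.209 and endothelial markers 0.537. In the libraries labelled LIN28B knockout alone p53 and apoptosis gave 0.574. In LIN28A knockout the median and the mean had opposite signs for fibroblast markers (−0.00 and 0.40), glycolysis (−0.00 and 0.02) and endothelial markers (−0.09 and 0.02), and meiosis had a median of 0.04 with a test pointing lower. In the libraries labelled LIN28B knockout they had opposite signs for the piRNA pathway (0.00 and −0.07) and insulin and IGF signalling (−0.03 and 0.06).

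Leaving out single libraries brought further lists past the threshold. Ribosomal proteins moved in opposite directions in the libraries labelled LIN28B knockout without replicate 2 (lower, adjusted p = 0.0243) and without replicate 3 (higher, adjusted p = 8.87e-08), and were lower in LIN28A knockout without LIN28A knockout replicate 3 (adjusted p = 1.95e-05) control replicate 1 or 3 (adjusted p = 0.0396 and 0.0319), or LIN28B knockout replicate 1, 2 or 3 (adjusted p = 0.0427, 0.0363 and 0.00501). In LIN28A knockout FGF and ERK targets were higher without LIN28A knockout replicate 3 (adjusted p = 0.00451), and mesoderm and endoderm genes lower without control replicate 3 (adjusted p = 1.86e-04). Without control replicate 2, pluripotency, let-7 targets and miRNA processing were lower and interferon response and leukocyte markers higher in LIN28A knockout (adjusted p = 0.0464 each), and leukocyte markers were higher without control replicate 1 (adjusted p = 0.0468). Pluripotency was lower in LIN28A knockout without LIN28A knockout replicate 1 (adjusted p = 0.0241) or 2 (adjusted p = 0.0199). In the libraries labelled LIN28B knockout FGF and ERK targets were higher without control replicate 3 (adjusted p = 0.0333), LIN28B knockout replicate 3 (adjusted p = 0.00722) or any LIN28A knockout library (adjusted p = 0.0348, 0.0375 and 0.00220). Without LIN28B knockout replicate 3, BMP signalling (adjusted p = 0.0406), interferon response (adjusted p = 0.0183), extracellular matrix and adhesion (adjusted p = 0.0237) and endothelial markers (adjusted p = 0.0200) were higher too. Endothelial markers were also higher without control replicate 1 (adjusted p = 0.0244), and pluripotency without LIN28A knockout replicate 3 (adjusted p = 0.0470).

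Between the knockouts the lists not named above did not pass: ribosomal proteins (camera adjusted p = 0.0611), piRNA pathway (0.0754), endothelial markers (0.0754), FGF and ERK targets (0.146), BMP signalling (0.146), erythroid markers (0.321), leukocyte markers (0.473), meiosis (0.554), let-7 targets (0.612), miRNA processing (0.632), S phase (0.632), insulin and IGF signalling (0.819), germ cell identity (0.941), interferon response (0.941) and ectoderm and neural genes (0.941). Of these lists the mixed test of fry passed for leukocyte markers (adjusted p = 1.77e-04), erythroid markers (6.26e-04), and germ cell identity and let-7 targets (0.0405 each). The mixed test also passed for the extracellular matrix list (0.0405) and fibroblast markers (0.0416), which did not pass camera. Without LIN28B knockout replicate 3, endothelial markers (adjusted p = 0.0175), FGF and ERK targets (adjusted p = 0.0175), BMP signalling (adjusted p = 0.0302) and ribosomal proteins (adjusted p = 2.20e-11) were lower in LIN28A knockout. Endothelial markers were lower as well without control replicate 1 or 3 (adjusted p = 0.0389 and 0.0377) or LIN28A knockout replicate 1 or 2 (adjusted p = 0.0367 and 0.0457). Without LIN28A knockout replicate 1 or 2, FGF and ERK targets were lower (adjusted p = 0.0328 and 0.0457), and without replicate 1 the piRNA pathway was higher (adjusted p = 0.0328). Ribosomal proteins were lower without LIN28A knockout replicate 3 (adjusted p = 1.16e-05).

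W chromosome genes had 2 tested members, too few for a test, with a median of −1.05 in LIN28A knockout against control. These were ATP5F1AW and HINTW, the latter at −0.98 ± 0.26 (edgeR adjusted p = 0.218). HINTW passed edgeR without LIN28A knockout replicate 3 (adjusted p = 0.00573) and DESeq2 on all libraries (adjusted p = 0.0228).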

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

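The tests below with a term for replicate 3, with replicates 1 and 2 only, and with the newer quasi-likelihood of edgeR were chosen after the result was seen, and the others before the data were examined. Direction held widely: of 88 values of named genes, all 88 kept direction and call with DESeq2 size factors, 85 with no filter and 85 of 85 with at least 5 CPM in 3 libraries. With DESeq2 in place of edgeR 54 of 88 were unchanged and 34 passed anew. With only the 2 groups compared 64 were unchanged and 24 no longer passed, with fewer libraries to inform the spread. All genes called by edgeR (1, 2 and 80) were also called by DESeq2 and with the replicate block. Of 78 list tests, 78 were unchanged with DESeq2 size factors, 55 with an estimated correlation and 60 with fry.

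Counts of called genes depended on the tool, and are given in the order LIN28A knockout, LIN28B knockout and LIN28A against LIN28B knockout. DESeq2 called 381, 158 and 1018 genes. With only the 2 groups compared edgeR called 0, 1 and 9. With no filter on low counts edgeR called 5 genes in LIN28A knockout and 136 between the knockouts, and the newer quasi-likelihood called 131 between the knockouts. A term for replicate 3 gave 265, 294 and 1737 genes, and replicates 1 and 2 only gave 4724, 4898 and 6196. Replicates 1 and 2 lie close together, which shrinks the spread, and leaving out replicate 3 also changes the fold changes. How much each adds to the rise was not tested. Leaving out single libraries gave 0 to 453, 0 to 166 and 0 to 474 genes, the highest in each case without LIN28A knockout replicate 3, the library farthest from its group.

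The replicate block, with the replicate number as the pairing, gave 13, 24 and 890 called genes. Between LIN28A and LIN28B knockout same-numbered libraries correlated at only 0.0331, 0.0517 and 0.0723, so the block count between the knockouts rests on a shared number alone. Against control the correlations bear only on setting replicate 3 apart, and matching replicates 1 and 2 rests on the number there too. With the replicate block p53 and apoptosis was lost in LIN28A knockout (adjusted p = 0.0986). Between the knockouts it was lost as well (adjusted p = 0.0889), as was glycolysis (adjusted p = 0.0683). The block changed no other call of a list against control than those given with the comparisons. Many of the named genes were chosen because they passed with the block or in the authors' deposited table, so a tally of calls gained among them is no test. Fibroblast markers in the libraries labelled LIN28B knockout changed sign at an adjusted p of 0.982 and interferon response between the knockouts at 0.730, both far from the threshold.

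Camera with an estimated correlation called 0, 0 and 0 lists, and fry called 1, 0 and 5, against 6, 8 and 9 with the preset correlation. The preset treats list members as nearly independent. The estimated correlation was close to it for some lists, such as p53 and apoptosis between the knockouts at 0.0181, and far from it for others, such as ribosomal proteins in LIN28A knockout at 0.765. It was far from it for called lists too. G2 and mitosis had 0.717 and the integrated stress response 0.456 in the libraries labelled LIN28B knockout. Extracellular matrix and adhesion had 0.243 in LIN28A knockout. The very small adjusted p values of these lists rest on the preset. Replicates 1 and 2 only lost p53 and apoptosis in LIN28A knockout (adjusted p = 0.0950) and between the knockouts (adjusted p = 0.411). The same setting lost mesoderm and endoderm in the libraries labelled LIN28B knockout (adjusted p = 0.127) and glycolysis between the knockouts (adjusted p = 0.194). Leaving out single libraries gave 6 to 10 lists in LIN28A knockout and 6 to 14 in the libraries labelled LIN28B knockout.

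The targeted genes kept their side of the threshold except with replicates 1 and 2 only, where LIN28A was at −0.43 in LIN28A knockout and LIN28B at 0.23 in the libraries labelled LIN28B knockout and passed. PRDM1 in LIN28A knockout was at −0.12 with replicates 1 and 2 only and between −0.0520 and 0.19 when single libraries were left out. In the libraries labelled LIN28B knockout, leaving out single libraries gave LIN28B between −0.0544 and 0.17, LIN28A between −0.0550 and 0.38, CXCR4 between −0.32 and 0.12 and MYC between −0.23 and 0.0141, so the signs of these values are not settled. The correlation of the knockout effects was 0.394 with no filter on low counts and 0.0913 to 0.321 when single libraries were left out. The cause was not tested.

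List tests that changed direction had lain far from the threshold in most cases, and the cause was not tested. Their adjusted p values follow. With no filter on low counts: ribosomal proteins in the libraries labelled LIN28B knockout 0.913, and between the knockouts germ cell identity 0.989 and ectoderm and neural 0.784. With at least 5 CPM in 3 libraries: germ cell identity 0.840 and FGF and ERK targets 0.737 in LIN28A knockout; let-7 targets 0.967, p53 and apoptosis 0.922 and leukocyte markers 0.922 in the libraries labelled LIN28B knockout; interferon response 0.720, ectoderm and neural 0.512 and meiosis 0.905 between the knockouts. With only the 2 groups compared, FGF and ERK targets in LIN28A knockout gave 0.946. Interferon response between the knockouts gave 0.961 with fry and 0.740 with a term for replicate 3.

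With replicates 1 and 2 only, direction changed in LIN28A knockout for piRNA pathway, let-7 targets and miRNA processing (adjusted p = 0.780 each) and for erythroid markers and endothelial markers (adjusted p = 0.903 each). In the libraries labelled LIN28B knockout it changed for p53 and apoptosis (adjusted p = 0.815). Between the knockouts it changed for let-7 targets (0.809), miRNA processing (0.707), S phase (0.539), insulin and IGF signalling (0.411), interferon response (0.707), ectoderm and neural (0.809) and leukocyte markers (0.984). The cause was not tested.

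Leaving out single libraries changed the direction of further lists, with these ranges of adjusted p. In LIN28A knockout: let-7 targets 0.0464 to 0.782, miRNA processing 0.0464 to 0.677, FGF and ERK targets 0.00451 to 0.988, activin and nodal signalling 0.448 to 0.992, BMP signalling 0.107 to 0.992, insulin and IGF signalling 0.107 to 0.782, mesoderm and endoderm 1.86e-04 to 0.964, meiosis 0.198 to 0.966 and endothelial markers 0.0920 to 0.823. In the libraries labelled LIN28B knockout: let-7 targets 0.226 to 0.923, miRNA processing 0.103 to 0.926, p53 and apoptosis 0.240 to 0.903, insulin and IGF signalling 0.154 to 0.999, ribosomal proteins 8.87e-08 to 0.982, fibroblast markers 0.102 to 0.966 and leukocyte markers 0.312 to 0.895. Between the knockouts: germ cell identity 0.716 to 0.961, let-7 targets 0.350 to 0.997, miRNA processing 0.327 to 0.687, S phase 0.146 to 0.857, insulin and IGF signalling 0.515 to 0.997, interferon response 0.416 to 0.961 and ectoderm and neural 0.409 to 0.993. The cause was not tested.

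Depth was alike across libraries, from 27.7 to 32.2 M counts, and the floor of 3 counts lay at 0.0931 to 0.108 CPM. At this depth genes under this level cannot be told from absent ones.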

Other observations

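Some genes chosen after their values were seen did not pass edgeR, but passed in the authors' deposited table. Values of both knockouts rest on the same control libraries. PRDM14, a regulator of germ cell identity, went from 118 ± 1.76 CPM in control to 158 ± 6.23 in LIN28A knockout and 158 ± 7.18 in the libraries labelled LIN28B knockout (SD, n = 3 each), a log2 fold change of 0.42 ± 0.09 (SE) in each (edgeR adjusted p = 0.151 and 0.325; 0.00378 and 0.00117 in the authors' deposited table). LHPP, a histidine phosphatase gene, was at 2.61 ± 0.33 in LIN28A knockout (edgeR adjusted p = 0.0655) and 2.14 ± 0.33 in the libraries labelled LIN28B knockout (edgeR adjusted p = 0.161), from 1.26 ± 0.05 CPM (n = 3) in control. LHPP passed DESeq2 (adjusted p = 2.46e-10 and 1.56e-06) and had 1.42e-08 and 5.25e-10 in the authors' deposited table. SOX17, a factor of endoderm and of germ cells in mammals, was at 2.60 ± 0.49 and 2.00 ± 0.48 (edgeR adjusted p = 0.126 and 0.393), with 8.05e-05 and 0.00838 in the authors' deposited table. ID2, a BMP target, was at −1.34 ± 0.29 and −1.19 ± 0.29 (edgeR adjusted p = 0.155 and 0.393). ID2 passed DESeq2 (adjusted p = 0.00159 and 0.0146) and had 0.00860 and 5.49e-11 in the authors' deposited table. PRTG, a let-7 target in vertebrate embryos, was at −0.94 ± 0.21 in LIN28A knockout (edgeR adjusted p = 0.171) and −0.09 ± 0.21 in the libraries labelled LIN28B knockout (edgeR adjusted p = 0.911). The difference in PRTG between the knockouts did not pass edgeR (adjusted p = 0.0992) and passed DESeq2 (adjusted p = 0.0112). PRTG in LIN28A knockout passed DESeq2 (adjusted p = 0.00737) and had 2.27e-07 in the authors' deposited table.

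The tests below on depth, on ATP5F1AZ and on other splits of the libraries were written before their results were seen. Those on a batch, on mixed cells, on loss of the W chromosome and on the stress response were chosen after the result was seen. Among the 10 ways to split 6 libraries into groups of 3, only the real split, 1 of 10 in each comparison, called as many genes as reported (1, 2 and 80), and the highest other count was 0. With 10 splits a share under 0.05 cannot be reached.

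LIN28A knockout replicate 3 lay 5.26 times as far from replicates 1 and 2 as these lay from each other, against 2.65 in control and 2.57 in the libraries labelled LIN28B knockout. The differences from control in replicates 1 and 2 hardly correlated with those in replicate 3 (r = 0.0541 over 10151 genes, against 0.463 in the libraries labelled LIN28B knockout). After thinning all libraries to 27.7 M counts the ratio was 5.16, so depth is unlikely to be the cause. Deviations of replicate 3 in the other groups accounted for 16.5% of the variance of its deviation, too little for a batch shared by the libraries numbered 3 to be the whole cause. If replicates 1 and 2 held cells like those of replicate 3 diluted with control-like cells, genes far from control in replicate 3 would move the same way in replicates 1 and 2, and only 51.7% of 816 such genes did: 63.0% of those higher in replicate 3 and 44.3% of those lower. The lower genes make dilution less likely as the whole cause, though a diluted fall is smaller on the log2 scale than a diluted rise and so harder to see. For the higher genes dilution stays open. LIN28A at 7.28% of control in replicate 3 and 72.8% and 76.2% in replicates 1 and 2 leaves different edited cells in the replicates as a possible cause that was not tested.

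The W-linked genes ATP5F1AW and HINTW were lower in value in LIN28A knockout: ATP5F1AW stood at 45.5%, 46.0% and 45.6% of the control mean in replicates 1, 2 and 3, and HINTW at 61.5%, 63.3% and 27.4%. In the libraries labelled LIN28B knockout ATP5F1AW was lower by less, at 75.2%, 80.4% and 89.1%, and HINTW stood at 101%, 87.7% and 97.3%. If reads of ATP5F1AW were counted for its Z-linked copy ATP5F1AZ, the copy would gain, but it changed by −133% of the CPM that ATP5F1AW lost. The oxidative phosphorylation list fell as a group (median −0.23), which could hide a gain of ATP5F1AZ, so this cause is not settled. Cells without a W chromosome at 1 share per library would lower ATP5F1AW and HINTW alike. The ratio of HINTW to ATP5F1AW lay outside the range of the other libraries, widened to 5.23 to 11.4, in 1 of 3 LIN28A knockout libraries (9.16, 9.32 and 4.08). The upper end of that range was set by LIN28B knockout replicate 1 at 9.12, where ATP5F1AW was itself lower. Every LIN28A knockout ratio lay outside the range of the control libraries alone, 6.54 to 7.25. The outcome thus turns on which libraries set the range, so this test cannot decide on the explanation. A steady ATP5F1AW beside a varying HINTW could also reflect regulation of each gene, which was not tested.

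The integrated stress response in the libraries labelled LIN28B knockout was lower in value in both sets of replicates. Its list median against the same-numbered controls was −0.55 in replicates 1 and 2 and −0.54 in replicate 3, with 24 of 29 members below 0 in both. Replicate 3 is here 1 library against 1 control library, and the list members are correlated (estimated at 0.456). The list median also ran from 0.01 to 0.68 within LIN28A knockout. This check therefore cannot exclude a difference carried by only 1 of the sets of replicates. The same list in LIN28A knockout was raised most in replicate 3 (median 0.68, against 0.14 in control replicate 3), and by less in replicates 1 and 2 (0.05 and 0.01, against −0.08 and −0.04). Without LIN28A knockout replicate 3 the integrated stress response still passed between the knockouts (camera adjusted p = 1.25e-12). With all libraries that call was itself lost at adjusted p = 0.488 with an estimated correlation.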
